A study of Mus musculus with 2 samples.

How the data were processed

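Total RNA above 200 nucleotides from hearts of newborn mice was depleted of ribosomal RNA by the authors and sequenced as stranded paired reads of 101 nucleotides, with ERCC spike-in RNAs added, per the labels. Both samples formed 1 group, newborn heart, with 2 biological replicates, and shared the same strain and donor label. The aligner, the program versions and the level of the deposited intervals are not given in the sources used here. The deposited notes name the mouse assembly mm10 and the GENCODE M4 annotation, and the column names are those of the quantification program RSEM.

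The deposited expected counts are maximum likelihood estimates of fragments per gene or transcript, with no normalization between libraries. The deposited TPM values are these counts divided by effective length and scaled to the same total over every entry of a table, spike-ins included. FPKM values, which the authors scaled by length and library total, served as an alternative for detection. The transcript share is, per the file headers, the percent of a gene's TPM in that transcript. Posterior mean estimates and interval bounds were also deposited and were used as alternatives and for a count of genes whose intervals did not overlap.

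Each gene table held 69691 entries, of which 43346 were genes, 96 ERCC spike-ins, 1 the phiX control and 26248 carried numeric identifiers and had 0 counts. Names and coordinates came from GENCODE M21 on GRCm38, matched by identifier without version, for 42462 genes, and 884 kept their identifier. Expected counts of genes summed to 69946215 and 73615802. Of 481 symbols in the lists, 476 were found, 6 of them under another name.

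A gene was detected at 1 TPM or more in both replicates. Differences between replicates were log2 ratios of TPM with a pseudocount of 0.1, centred on the median of genes at a mean of 1 TPM or more, and a difference of 2-fold or more was counted. Correlations were across genes on log2 of TPM plus 1. For 41 gene pairs the log2 ratio within each replicate was set against the 95th percentile of the absolute differences between replicates, 2.15. For 35 gene lists the detected members were counted, and for lists with at least 5 members at a mean of 1 TPM the median difference was placed among 10000 random lists of equal size, matched on level in 20 bins. The lists were sarcomere, calcium handling, ion channels and conduction, cardiac transcription factors, atrial, ventricular, fatty acid oxidation, glycolysis, nuclear and mitochondrial oxidative phosphorylation, cell cycle, cell-cycle inhibitors, replication-dependent histones, fibroblast and matrix, endothelial, endocardial, smooth muscle and pericyte, epicardial, macrophage, lymphocyte and thymus, erythroid, platelet, Schwann and neuronal, lung, liver, skeletal muscle, adipose, imprinted, long noncoding, structured noncoding, sex-linked, immediate-early, hypoxia, growth signalling and housekeeping. Leading transcripts were counted for genes with at least 2 annotated transcripts and a mean of 5 TPM, and a share of 80% was called major. With 1 group there was no test between groups. The groups, lists, pairs, thresholds, most alternatives and the rule for named genes were fixed before the data were examined.

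The named genes were the 15 nuclear genes of highest mean TPM with the highest mitochondrial and structured noncoding genes, up to 4 members of each list with the highest mean TPM, list members under 0.1 TPM in both replicates as absent, all genes of the pairs, the 10 genes with the largest difference in each direction at a mean of 1 TPM and a summed count of 100, and a fixed set of genes for transcript usage. Irx4, Krt19, Wt1, Lrrn4 and Tbx18, named in the report, fell outside this rule and were chosen after their values were seen. Counting intervals and the floor of 3 counts for a count of 0 cover counting error alone. The variance of counts between replicates was compared with their mean, with 1000 bootstrap resamples.

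Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 20. TMM factors came from edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers. Alternatives covered thresholds, pseudocounts, filters, scaling, units, estimates and single replicates. The calls of 2-fold differences, the variance-to-mean ratio and the list percentiles were tested on simulated data, while pair calls, transcript shares and the regression on GC content and length were not. With read counting alone, 34.2% of genes set 2-fold apart and 100% of those set 4-fold apart were called, and 0.0263% to 0.0350% of unchanged genes were. With a variance 100 times the mean the shares called were 49.2% at 2-fold and 93.3% at 4-fold, and 13.3% to 13.7% of unchanged genes were called. Both simulated libraries used the effective lengths of replicate 1. The simulation thus left out differences in TPM that come from a change of effective length between libraries. Simulated genes were drawn independently of each other, so the simulation could not show how lists of genes that vary together behave. The raw reads, phiX and the numeric identifiers were not analysed here.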

Results

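Hearts of newborn mice were profiled by total RNA sequencing, a method that reads all RNA classes above a size limit after ribosomal RNA has been depleted. The design held 1 group, hearts taken at postnatal day 0 from pools of mice of both sexes, with 2 biological replicates made from independent tissue isolates. Replicate 1 was a pool of 15 mice, and the number pooled for replicate 2 was not given. Expected counts summed to 71186117 in replicate 1 and 75105452 in replicate 2. No second tissue, age or treatment was part of the series, so the data address which genes the newborn heart expressed, how paired gene forms compared within it, and how far the 2 isolates differed. Values are TPM, an abundance relative to all transcripts of the library after division by length, given as mean ± SD with n = 2 unless each replicate is named.

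Atp5b, which encodes the beta subunit of ATP synthase, and Actc1, the cardiac alpha-actin gene, had the highest mean TPM among messenger RNAs of the nuclear genome. Atp5b was at 6157 TPM in replicate 1 and 5163 in replicate 2 (ENSMUSG00000025393.8, GRCm38 chromosome 10, 128083273 to 128090391). Actc1 was at 5636 and 5468 TPM, above Atp5b in replicate 2 and above it by counts in both replicates (ENSMUSG00000068614.7, chromosome 2, 114047282 to 114053548). Myl2 and Myl3, which encode ventricular myosin light chains, stood at 2129 ± 219 and 2100.4 ± 302 TPM. The mitochondrial genome supplied 21.4 ± 0.433% of TPM, and its highest messenger RNA was mt-Co1, a subunit of cytochrome c oxidase, at 23626 ± 78.9 TPM. Structured noncoding RNAs of the nuclear genome took 47.0 ± 0.619% of TPM but 1.98% of expected counts, since TPM divides by their short lengths. Rn7sk, which controls transcription elongation, reached 123374 ± 27110.2 TPM, and Rpph1, the RNA of ribonuclease P, was at 38067 in replicate 1 and 93839 in replicate 2. Sarcomere genes took 1.88 ± 0.0453% of TPM, globins 0.340 ± 0.0432% and the added spike-in RNAs 1.63 ± 0.174%. A TPM of at least 1 was reached in both replicates by 10471 genes, of which 10112 were protein-coding, with 881 more in replicate 1 alone and 977 in replicate 2 alone.

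Genes of the contraction machinery were among the most abundant. All 21 sarcomere genes listed reached 1 TPM in both replicates, with a summed level of 18750.1 ± 453 TPM, led by Actc1, Myl2, Myl3 and Myh6. All 16 calcium-handling genes did so too, among them Atp2a2, the sarcoplasmic reticulum calcium pump, at 559 ± 4.43 TPM (ENSMUSG00000029467.11, chromosome 5, 122453513 to 122502225). Its inhibitor Pln stood at 521 ± 43.2 TPM, the sodium-calcium exchanger Slc8a1 at 255 ± 10.8 and Srl, a sarcoplasmic reticulum protein, at 247 ± 9.33. Of 21 ion channel and gap junction genes, 16 were detected in both replicates, with the potassium channel subunit Kcne1 at 61.4 ± 19.4 TPM, the gap junction gene Gja1 at 51.6 ± 1.54 and Kcnh2 at 27.0 ± 5.76. Among 24 cardiac transcription factors, 21 were detected in both replicates, and the highest were Tbx20 at 148 ± 8.43 TPM, Hopx at 140.3 ± 10.3, Nkx2-5 at 81.0 ± 12.9 and Gata6 at 69.2 ± 19.95. All 12 atrial and all 9 ventricular genes were detected, which included Nppa, the atrial natriuretic peptide gene, at 777 ± 143 TPM and the ventricular repressor Irx4 at 19.6 ± 4.19.

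The newborn heart expressed the cardiac member of several contractile gene pairs far above its skeletal counterpart. A pair was called unequal when its log2 TPM ratio had the same sign in both replicates and exceeded in each 2.15, the 95th percentile of differences of single genes between the replicates. The call was made for 8 of 11 contractile pairs and for 3 of 4 calcium pairs, with the first-named gene higher in each. Not every second gene was a skeletal form: Myl4, below Myl3, is in the atrial list, and Acta2, below Actc1, in the smooth muscle list. Actc1 exceeded Acta1, the skeletal alpha-actin gene, by 7.004 and 5.62 on the log2 scale in replicates 1 and 2. Tnnt2 exceeded Tnnt1, the slow skeletal troponin T gene, by 6.02 and 6.12. The ratio of Atp2a2 to the skeletal pump gene Atp2a1 was 8.98 and 10.69. Ryr2 exceeded Ryr1 by 8.75 and 8.94, with Ryr1 under 0.1 TPM in both replicates. With the 99th percentile as the limit, 10 of the 41 pairs were called in place of 19.

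The myosin heavy chain and troponin I pairs did not differ beyond the spread between replicates. Myh6, the alpha myosin heavy chain gene of the adult mouse ventricle, was at 1390.5 ± 59.3 TPM (ENSMUSG00000040752.11, chromosome 14, 54941921 to 54966927), and Myh7, the beta form, at 1042 ± 45.1 (ENSMUSG00000053093.11, chromosome 14, 54970684 to 54994626). Their log2 ratio was 0.33 and 0.50, inside that limit and inside the limit of 1.28 from genes at a mean of 10 TPM. It was -0.12 when counts were not divided by length. Tnni3, the cardiac troponin I gene, at 1330.5 ± 135 TPM, and Tnni1, the slow skeletal and fetal form, at 1152 ± 87.0, gave 0.18 and 0.23, against -0.98 in counts not divided by length. Between the replicates Myh6, Myh7, Tnni3 and Tnni1 differed by 0.06, -0.11, 0.19 and 0.13 on the log2 scale, so the limits are wide for these genes. The ventricular Myl2 exceeded the atrial Myl7 by 1.48 and 2.49, past the limit in replicate 2 alone. Nppa and Nppb, the natriuretic peptide genes, gave 1.51 and 1.62. Both of these pairs were called unequal in counts not divided by length, where Nppa over Nppb, at 1.737 and 1.85, barely passed the limit of 1.736, and with the limit of 1.28 from genes at a mean of 10 TPM, and Nppa and Nppb also with a pseudocount of 1.

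**Figure D1:**
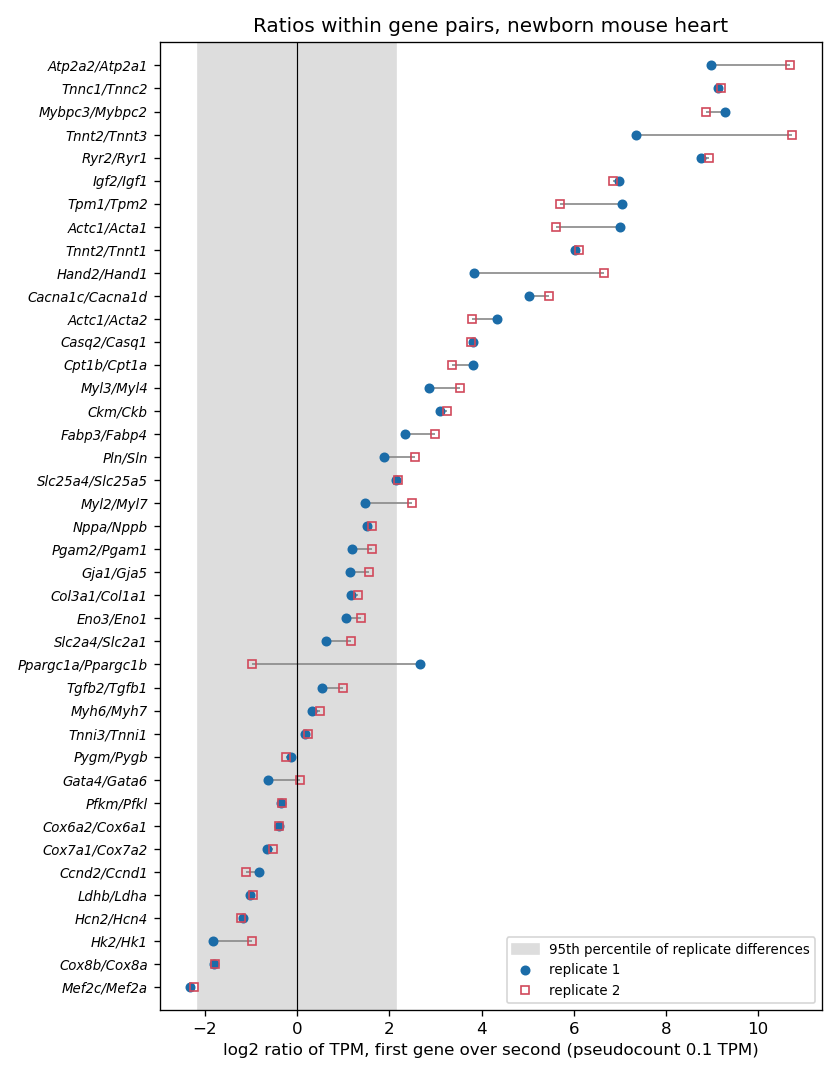
Log2 ratio of TPM of the first over the second gene of 41 pairs (x axis), replicate 1 as filled circles and replicate 2 as open squares joined by a line; the grey band is the limit of 2.15. Of the pairs, 19 lay outside the band with the same sign in both replicates, from Mef2c/Mef2a on the left to Atp2a2/Atp2a1 on the right.

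Genes of energy metabolism were expressed throughout, with muscle and ubiquitous forms side by side. All 22 genes of fatty acid oxidation, all 19 of glycolysis, all 25 nuclear and all 13 mitochondrial genes of oxidative phosphorylation were detected in both replicates. Fabp3, the heart fatty acid binding protein, was at 786 ± 350.4 TPM (ENSMUSG00000028773.8, chromosome 4, 130308595 to 130315463). Gapdh was at 1856 ± 132 TPM, Aldoa at 1149.5 ± 3.89, Atp5a1 at 1387 ± 4.31 and mt-Co3 at 11943 ± 1567. Of 15 metabolic pairs, 4 were called unequal. The muscle creatine kinase Ckm exceeded the brain form Ckb by 3.09 and 3.25 on the log2 scale, and the muscle carnitine palmitoyltransferase Cpt1b exceeded the liver form Cpt1a by 3.81 and 3.35. Fabp3 exceeded Fabp4 by 2.34 and 2.99, and the adenine nucleotide carrier Slc25a4 exceeded Slc25a5 by 2.15 and 2.19. The Fabp3 and Slc25a4 calls were lost with posterior mean TPM, whose limit was 2.43, and all 4 were lost with the 99th percentile as the limit, 4.85. Ldhb, the lactate dehydrogenase form dominant in the adult heart, lay below Ldha, with log2 ratios of -1.03 and -0.95 that did not exceed the limit. The coactivator genes Ppargc1a and Ppargc1b had a ratio of 2.66 in replicate 1 and -0.99 in replicate 2, but 2.74 and 2.53 in counts not divided by length, since the effective length of Ppargc1b was 3330.1 nucleotides in replicate 1 and 404 in replicate 2.

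Igf2 and some other imprinted genes were abundant. Igf2, an imprinted growth factor, stood at 388 ± 55.8 TPM (ENSMUSG00000048583.12, chromosome 7, 142650766 to 142666816) and exceeded Igf1 by 6.98 and 6.86 on the log2 scale. Of 22 imprinted genes, 21 were detected in both replicates, with the long noncoding RNA H19 at 637 ± 127 TPM, Mest at 608 ± 265 and Gnas at 307 ± 11.1. Of 19 growth-signalling genes, 18 were detected, among them Ccn2 at 83.9 ± 19.8 and Vegfa at 40.9 ± 13.9. All 28 cell-cycle genes were expressed, with the cyclin Ccna2 at 59.8 ± 20.2 TPM, Pcna at 40.6 ± 4.24, Cdk1, the kinase that drives entry into mitosis, at 36.9 ± 18.2 and Ccnb2 at 25.1 ± 11.5. All 20 replication-dependent histone genes were detected, led by Hist1h4d at 4029 ± 713, and 6 of 8 cell-cycle inhibitors were, led by Cdkn1c at 28.7 ± 8.75, while Cdkn2a had 0 counts in both replicates. The regulator pairs Mef2a over Mef2c, with a Mef2c/Mef2a ratio of -2.33 and -2.23, and Hand2 over Hand1, at 3.84 and 6.66, were called unequal. The Mef2 call was lost with posterior mean TPM, in counts not divided by length and with the 99th percentile as the limit, and the Hand call with the last of these. Gata4 and Gata6 were not, at -0.63 and 0.07. Of 15 long noncoding RNAs listed, 13 were found in the data and 9 were detected, with Malat1 at 621 ± 81.5 TPM, while Hotair and Miat had 0 counts.

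Markers of the other cell types of the heart were present. All 19 fibroblast and matrix genes were detected in both replicates, among them Vim at 694 ± 37.3 TPM and Sparc, a matrix protein, at 204 ± 23.7. All 17 endothelial genes were detected, with Fabp4 at 118 ± 16.7 and Egfl7 at 102 ± 3.73, and so were 4 of 5 endocardial genes, led by Plvap at 19.7 ± 8.75. All 11 smooth muscle and pericyte genes and all 10 epicardial genes were detected. So were 8 of the 13 macrophage genes found in the data, led by C1qb at 13.5 ± 4.84. Blood was represented by 5 of the 13 erythroid genes found in the data, with Hba-a2 at 1619 ± 97.4 TPM. Of 5 platelet genes 2 were detected, with Pf4 at 11.8 and 27.2 TPM. Embryonic Hbb-bh1 and the erythroid regulator Klf1 had 0 counts in both.

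Most markers of neighbouring tissues were low, and some differed between the replicates. The 14 lymphocyte and thymus genes summed to 9.34 TPM in replicate 1 and 0.74 in replicate 2, and none reached 1 TPM in both. Rag1, needed for antigen receptor rearrangement, had 2138 counts in replicate 1 and 8 in replicate 2, while Foxn1 had 1 and 0. The 8 lung genes summed to 5.31 and 1.93 TPM, with Scgb1a1 at 46 and 0 counts. Of 17 skeletal muscle genes, 4 were detected in both, namely Ckm, Acta1, Myh8 and Tnnc2, and the myogenic regulators Myod1, Myog, Myf5 and Myf6 had 0 counts. Among 9 liver genes 3 were detected, led by Ahsg at 14.0 ± 3.63 TPM, and the list summed to 24.97 and 30.76 TPM. None of the 12 Schwann cell and neuronal genes was detected in both, and 2 of 8 adipose genes were, Cidea at 4.14 and 11.2 TPM and Prdm16 at 2.55 and 2.45 TPM, while Ucp1 and Lep had 0 counts. By counting error alone a count of 0 allows up to 3 counts. The spread between the libraries, given below, allows more, and differences such as that of Scgb1a1 were not set against it.

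Genes of fat metabolism, proliferation and smooth muscle differed between the replicates as groups. Of the 22 fatty acid oxidation genes, 19 were higher in replicate 2, with a median log2 difference of 0.33, and Fabp3 was at 538 in replicate 1 and 1034 in replicate 2. Of the 28 cell-cycle genes, 20 were lower in replicate 2, with a median of -0.43, and Cdk1 was at 49.8 and 24.0 TPM (ENSMUSG00000019942.8, chromosome 10, 69335146 to 69352938). In counts Cdk1 differed less, with 4012 and 2903, because its effective length was 763 and 1089.8 nucleotides, while the list's median in counts was -0.38. All 11 smooth muscle and pericyte genes were higher in replicate 2, with a median of 0.50, and Tagln, an actin-binding protein of smooth muscle, was at 16.8 and 160.4 TPM (ENSMUSG00000032085.4, chromosome 9, 45929619 to 45936058). Of 29 lists with at least 5 members at a mean of 1 TPM, 10 had medians outside the middle 95% of 10000 random lists matched on level, 5 above and 5 below. By chance 1.45 would fall outside if the genes within a list varied independently of each other. Genes that vary together would put more lists outside, and some lists share genes. Single genes of other tissues also differed, with the lymphoid Rag1 at 3.20 and 0.01 TPM and the bladder epithelium gene Upk3a at 0.07 and 32.6 TPM.

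The other lists above that range were epicardial genes, with a median of 0.79 at percentile 99.92, fibroblast and matrix genes, with 0.29 at percentile 99.75, and immediate-early genes such as Jun and Dusp1, with 0.43 at percentile 97.93, which a pseudocount of 1 TPM brought back inside the range. In the epicardial list the keratin Krt8 was at 4.53 and 31.4 TPM and Upk1b at 5.01 and 20.5, while Upk3b was at 18.3 and 16.8. The 5 members that were 2-fold higher were Krt8, Krt18, Krt19, Upk1b and Wt1, of which the keratins and Upk1b are also expressed in bladder and other epithelia, and Upk3b, Lrrn4 and Tbx18 were lower. The lists below the range were replication-dependent histones, with a median of -0.29 at percentile 0.15, cell-cycle inhibitors, with -0.69 at percentile 0.38, imprinted genes, with -0.32 at percentile 0.575, and atrial genes, with -0.38 at percentile 0.98. Cell-cycle genes and their inhibitors were thus lower together in replicate 2. Smooth muscle genes stood at percentile 99.73, fatty acid oxidation at 99.99 and cell-cycle genes at 0.02. With 1 library on each side these are descriptions of 2 libraries, and no p-value was computed, since an exact two-sided sign-flip test over 2 replicates cannot give less than 0.5.

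Several cardiac muscle lists, unlike the atrial list, had medians inside the range of random lists. The medians of sarcomere, calcium-handling and channel genes were 0.04, 0.01 and 0.04, at percentiles 75.6, 60.2 and 64.4, and cardiac transcription factors and ventricular genes had -0.02 and 0.19, at percentiles 45.3 and 89.995. The sign of the channel median was not stable, since it was -0.12 without a filter and -0.11 in counts not divided by length, at percentiles 15.7 and 14.4. In those counts calcium-handling, endothelial and mitochondrial oxidative phosphorylation genes also changed sign, to -0.02, 0.10 and 0.01, all inside their ranges. Glycolysis, nuclear and mitochondrial oxidative phosphorylation had medians of -0.10, 0.01 and -0.03, at percentiles 23.1, 64.4 and 43.5. Endothelial, macrophage and erythroid genes had -0.04, -0.22 and 0.28, at percentiles 44.1, 16.8 and 94.5. Liver and skeletal muscle genes had -0.04 and -0.35, at percentiles 43.2 and 13.5, and in counts not divided by length the skeletal muscle median was -0.61, at the edge of its range. Hypoxia, growth-signalling and housekeeping genes had -0.11, -0.02 and -0.17, at percentiles 31.6, 49.2 and 16.1, with growth signalling near 0 on either side under other settings. Long noncoding, structured noncoding and sex-linked genes had 0.04, -0.04 and -0.10, at percentiles 64.9, 44.4 and 38.3. In counts not divided by length the sex-linked median was 0.68, outside its range at percentile 97.9. Its members went both ways by TPM, with 2 higher and 3 lower in replicate 2. Xist, the RNA that silences an X chromosome, was at 17.2 and 7.92 TPM. Of the Y-linked genes, Uty was at 2.97 and 4.53 TPM, Eif2s3y at 6.28 and 4.51 and Ddx3y at 4.37 and 4.13. In counts Uty had 861 and 1523, Eif2s3y 842 and 770 and Ddx3y 755 and 1262, while Xist had 31734 and 15333. Kdm5d, also Y-linked, was the 1 member at least 2-fold higher by TPM in replicate 2, and Xist the 1 at least 2-fold lower. The list joins Xist with Y-linked genes, so its median has no single reading. Whether the pools differed in their mix of sexes was not tested.

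**Figure D2:**
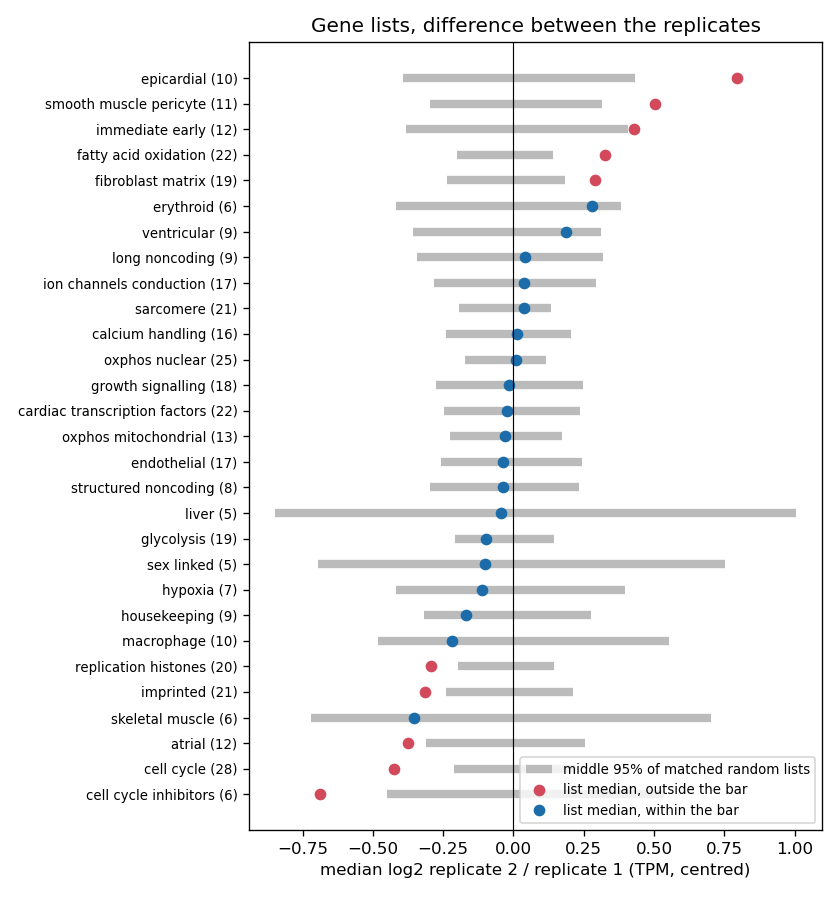
Median log2 difference of replicate 2 over replicate 1 (x axis, TPM, centred on all genes) of the 29 lists, with the number of members at a mean of 1 TPM or more in brackets; grey bars span the middle 95% of 10000 matched random lists. Red points, 10 in all, lie outside their bar, from cell-cycle inhibitors at -0.69 to epicardial genes at 0.79.

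Among single genes, Upk3a, a structural protein of the bladder epithelium, was at 0.07 TPM in replicate 1 and 32.6 in replicate 2, from 6 and 2950 counts (ENSMUSG00000022435.5, chromosome 15, 85017141 to 85022547). Sprr1a, an epithelial envelope protein, had 1 and 672 counts, and Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, 0 and 689. The T cell receptor gene Trbc2 had 524 and 0 counts. Of the 20 genes with the largest differences, 8 had an effective length under 20 nucleotides in a replicate, where TPM is unstable. The 4 copies of the spliceosomal U2 RNA among them, Gm24950, Gm23971, Gm23849 and Rnu2-10, were at 832 and 0 TPM each from 136 and 187.5 counts. Patj, a cell polarity gene, was at 2.35 and 343.5 TPM from 1075 and 1481 counts.

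Across 11594 genes at a mean of 1 TPM or more, 1171 were at least 2-fold higher and 1032 at least 2-fold lower in replicate 2, together 19.001%. Replicate 2 was the higher for 53.2% of these, for 45.2% with posterior mean TPM and for 34.7% when the spike-ins set the scale, which moved the median of all genes by -0.27 on the log2 scale. The 2-fold share was 40.8% at 1 to 2 TPM and 5.47% at 100 TPM and above. Of the 2203 genes, 1441 also differed 2-fold in the same direction by counts. Pearson's correlation across these genes was 0.897 and Spearman's 0.865; genes are not independent replicates. The variance of protein-coding gene counts between the replicates was 106 times their mean for counts from 100 to 10000, where read counting alone gives 1. For 29 spike-in transcripts it was 85.6 times, with their counts scaled by the factor of the genes, which adds to their ratio. Deposited intervals did not overlap for 8500 genes, 73.3%, so they do not cover the spread between libraries.

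**Figure D3:**
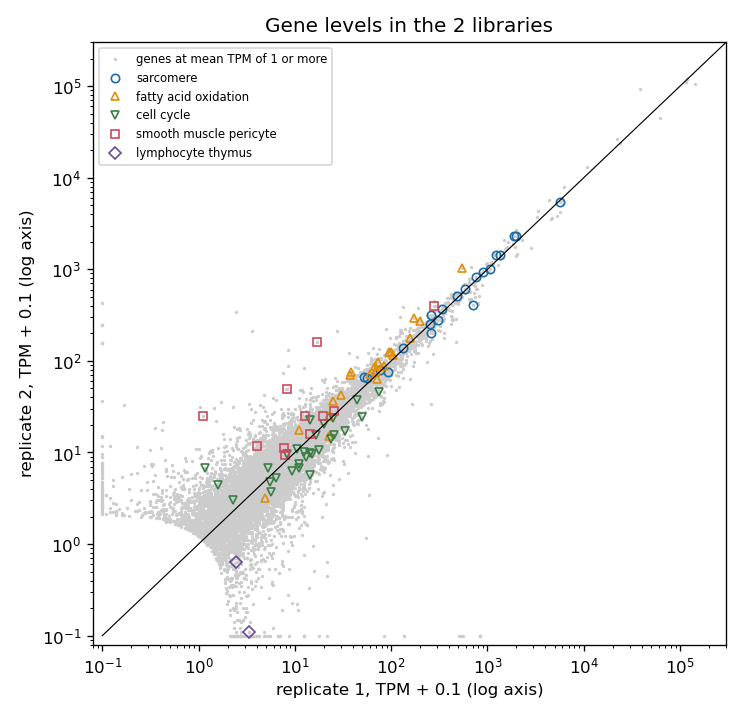
TPM of each gene in replicate 1 (x axis) and replicate 2 (y axis), log axes with 0.1 TPM added, for 11594 genes in grey and the members of 5 lists as coloured symbols; the line marks equal levels. Smooth muscle genes lay on or above the line and the 2 lymphocyte genes plotted lay under it.

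**Figure D4:**
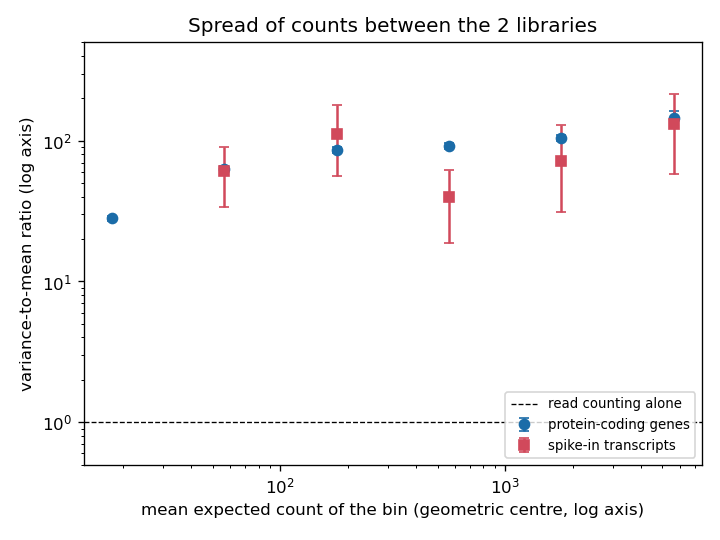
Variance-to-mean ratio of counts between the replicates (y axis, log) by mean count (x axis, log) for protein-coding genes and spike-in transcripts; points are bin means with 95% bootstrap intervals, and the dashed line is read counting alone. From 100 to 10000 counts the gene means lay between 85.9 and 145. Counts of both classes were scaled by the factor of the genes.

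For several muscle genes a single transcript carried nearly all of the expression in both replicates. The leading transcript of Ryr2 carried 98.8 ± 0.00707% of the gene's TPM, that of Actn2, which encodes the Z-disc protein alpha-actinin, 98.2 ± 1.36%, that of Myh7 97.7 ± 0.566%, that of Atp2a2 93.9 ± 1.06% and that of the tropomyosin gene Tpm1 92.5 ± 2.23%. Ttn, the titin gene, had its leading transcript at 44.9 ± 0.714%, and Tnnt2 at 24.7 ± 7.70% among 15 transcripts. In counts the leading Ttn transcript, of 81843 nucleotides, held 965853 of 1106017 in replicate 1 and 1039919 of 1197338 in replicate 2. Its TPM share is lower because TPM divides by length. Pkm-202, of the pyruvate kinase gene Pkm, held 78.4 ± 0.955%. The leading transcript of Gnas was at 54.0% in replicate 1 and 76.3% in replicate 2. Of 5113 genes with at least 2 transcripts and a mean of 5 TPM, the same transcript led in both replicates for 3672, 71.8%, a share that was 92.0% for genes at 100 TPM and above. A transcript held at least 80% of TPM in both replicates for 1566 genes.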

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

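No test in this part was chosen after the result was seen. Counts assigned to the phiX control, a viral genome run alongside libraries on a sequencer, lie outside every comparison of the report. These counts exceeded the 3 counts that a count of 0 allows by counting error alone. They were 338052 in replicate 1 and 391791 in replicate 2.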

How the results depend on the processing

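Alternatives that used expected counts without division by length for differences and list medians, and a count of 100 for detection, were chosen after the data were seen. Requiring 5 TPM left 5886 detected genes. As shares of expected counts, the mitochondrial genome took 32.5%, structured noncoding RNA 1.98%, globins 0.175%, sarcomere genes 5.81% and spike-ins 1.36%, because counts are not divided by length. The correlation was 0.832 and 0.768 with pseudocounts of 0.1 and 0.01, 0.965 over all genes, 0.876 at a mean of 5 TPM and 0.865 by Spearman's method. Genes 2-fold higher in replicate 2 numbered 2276 at a mean of 0.1 TPM, 433 at 5 TPM, 2506 without a filter and 1875 after rescaling without mitochondrial and structured RNA and spike-ins. Genes 2-fold lower numbered 2200, 323, 2374 and 1707 under the same settings, 650.0 with a pseudocount of 1 and 1555 with spike-in scaling. TMM and median-of-ratios factors moved the median of all genes by 0.02 on the log2 scale each. Replicate 2 held 45.2% of 2-fold genes with posterior mean TPM. In counts, the U2 copies Gm24950, Gm23971, Gm23849 and Rnu2-10 were higher in replicate 2, each by 0.38 on the log2 scale, since their effective lengths of 1.55 and 0 nucleotides set their TPM. With the 99th percentile as the limit, 10 pairs were called unequal. The median of immediate-early genes was 0.35 with a pseudocount of 1, inside the range of random lists. A transcript was major in both replicates for 2484 genes at a mean of 1 TPM, 626 at 20 TPM and 3014 at a share of 50%. Except where construction shows it, the cause was not tested. With single replicates, detected genes ranged from 11352 to 11448 and unequal pairs from 20 to 21. Of the other recomputed values, 117 for main results and 584 for single genes, pairs and lists kept their direction and side of the threshold or moved by less than the spread, while 29 single values moved, 17 passed a threshold they had missed and 14 fell short of one they had passed. No paired analysis was possible because there was 1 group, and leaving out a replicate leaves no difference between replicates. Genes at 1 to 2 TPM had a median of 336 counts, about 3.16 independent counts at the measured spread, which limits what their differences show.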

Other observations

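The gene families and the single genes in the next paragraph were chosen after their values were seen, as were the tests of the spread of counts on its slope and on spike-ins, the test of gut lining genes and the rules on spread and on the number of genes applied to the urothelial, Hox and intestinal genes. Ribosomal protein genes were expressed at a summed 15550 ± 115 TPM (SD, n = 2), with 76 of 79 detected in both replicates and a median log2 difference of -0.02. Proteasome genes, 36 of 39 detected, had a median of -0.03. Of 44 collagen genes 22 were detected, with a median of 0.26 at percentile 98.37, and Col3a1, a fibrillar collagen, was at 182 ± 41.0 TPM. Of 47 mitochondrial carrier genes 33 were detected, with a median of 0.22 at percentile 98.62. Of 15 Hox genes of the anterior groups, none reached 1 TPM in both replicates.

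Further single genes differed between the replicates. Actg2, a smooth muscle actin of hollow organs, was at 3.45 TPM in replicate 1 and 214 in replicate 2, Myh11 at 1.01 and 24.97, and Cnn1 at 8.14 and 49.0. The bladder epithelium genes Upk1a and Psca were at 0.33 and 21.3 and at 0.25 and 18.5 TPM. In the other direction, the thymus protease Prss16 had 674 and 0 counts, the airway gene Scgb3a1 510 and 12, and the skeletal muscle genes Mylpf and Cacna1s 290 and 1 and 219 and 0, while the skeletal actin gene Acta1 was at 43.8 and 111 TPM. None of these genes was set against the measured spread on its own. For 0 and 274 counts, the sum of the Hox genes below, the difference was 1.61 SD of that spread, taken at the ratio of 106 from genes at 100 to 10000 counts. Differences as small as those of Mylpf and Cacna1s can thus lie within it.

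The first pattern weighed was that counts of a gene lay further apart between the libraries than read counting allows. Differences in level between the pooled hearts do not account for it alone, because spike-in RNAs had a variance 85.6 times their mean, nor do reads shared between similar genes, because genes with whole counts in both libraries had a ratio of 105. A candidate explanation is that few molecules were each read many times, for which the ratio would change little with the count: its slope on the log10 scale was 0.148 between 100 and 10000 counts. Above 10000 counts the ratio was 468 for protein-coding genes and 1418 for 11 spike-in RNAs. The value for genes is more than this explanation alone gives, and what adds to it was not tested. Spike-in counts were scaled by the factor of the genes, although spike-in TPM was higher in replicate 2 by a median of 0.29 on the log2 scale. That offset raises their ratio most at high counts, so the 1418 does not measure spread alone. From 100 to 316 counts, where the offset matters less, the spike-in ratio was 112. No comparison between groups was possible, since the design held 1 group.

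The second pattern was that smooth muscle and epithelial genes were higher in replicate 2. More vessel wall alone does not account for its epithelial part, because 14 urothelial genes whose values had not been seen summed to 1065 and 4981 counts, 4.88 SD of the measured spread apart. The 4 of them at a mean of 1 TPM, where 5 were otherwise required, had a median at percentile 99.97, but Krt15 and Cldn4 passed that filter through replicate 2 alone, and Krt13 and Krt20 had 0 counts in both replicates, Epcam 0 and 1, and Gata3 72 and 0. Krt7 alone had 540 and 2741 counts. Upk3a and Krt8 had already been seen to be higher when the pattern was set, so this list could add little. It does not show whether more vessel wall raised the smooth muscle genes. Tissue from the bladder or another hindbody organ and tissue from the gut both passed the 2-fold thresholds written before their values were seen. Hox genes of groups 9 to 13 had 0 and 274 counts, 200 of them from Hoxa10 alone. That is 91.3 times a floor of 3 counts, which is no lower bound at the measured spread. Intestinal genes had a ratio of 5.96. How these results were read was revised more than once after the values were seen, and both sources stay open: the Hox difference was 1.61 SD of the spread, under the 2 SD asked for, and the intestinal difference was 2.38 SD but came from 2 of 9 genes, Lgals4 and Apoa4, with 1 lower and 6 at 0 in both replicates. These SD values all used the ratio of 106 from genes at 100 to 10000 counts. The Hox genes other than Hoxa10 had 45 counts or fewer. Protein-coding genes had a ratio of 63.3 at 31.6 to 100 counts and 28.2 at 10 to 31.6 counts. That the Hox difference was under 2 SD thus depends on the ratio used. The 0 counts of the gut lining genes Fabp1, Fabp2, Vil1, Cdx1 and Cdx2 exclude nothing by themselves, because those genes were picked once known to be at 0.

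The third pattern was that fatty acid oxidation genes were higher and cell-cycle genes lower in replicate 2. GC content and transcript length do not account for it: after regression on both, which explained 0.702% of the variance of the differences, the lists stood at percentiles 99.92 and 0 among random lists. A candidate explanation is that the hearts of replicate 2 were more mature or better fed, for which other targets of the fatty acid receptor PPARA would be higher and genes of fetal growth lower. The PPARA targets, 15 of 16 higher and several of them also fatty acid oxidation enzymes, stood at percentile 100, and the fetal growth genes, 10 of 13 lower, at percentile 0.5. Other values do not go with it. Ppara itself was at 4.83 and 3.08 TPM, cell-cycle inhibitors were lower with a median of -0.69, and nuclear oxidative phosphorylation genes had 0.01. Ppargc1a was at 22.3 and 15.0 TPM, but its counts, 8124 and 7732, differed less, since its effective length was 3456 and 4663 nucleotides. Age in hours and feeding were not in the labels, and a different mix of cell types was not excluded. The hypothesis was found and tested on the same 2 libraries.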
